A study of Mus musculus with 79 samples.

How the data were processed

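RNA of nuclei from mouse visual cortex was measured in 79 libraries. Per the labels' protocols, the mice were injected in the visual cortex with an adeno-associated virus (AAV) at postnatal days 55 to 60 and placed in the dark 3 days later for 10 to 12 days. Cortices were frozen, nuclei were isolated, and 50 to 100 nuclei per library were sorted by flow cytometry directly into lysis buffer. Reverse transcription was primed with an oligo-dT primer, the cDNA was amplified by 17 cycles of PCR, and libraries were made with the Nextera XT kit, a transposase kit that does not mark strand. The protocol text names harvest in the dark and harvest after re-exposure to light, whereas every library's own label gave 10 days of dark housing; the analysis followed the library labels.

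The values used were whole-number counts per gene, deposited by the authors as 1 table of 55335 genes and 79 libraries with no normalization. The submitters' processing notes name cutadapt 1.18, STAR 2.5.3a, HOMER 4.9.1 and the mm10 genome, with neither role nor order. The annotation behind the counts, the counting settings and the use of strand were not given in the sources used here. Reads of overlapping genes on opposite strands, such as Dlx1, Dlx6os1 and their neighbours, therefore could not be separated with certainty, and neither could reads of close paralogs such as the H2-K1 and H2-Q genes. Every column matched 1 library title and 0 columns were left over. Gene identifiers were matched to the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names: 55154 matched and 181, with 0.0264% of all counts, did not. Mitochondrially encoded genes held 0.492% of counts, 213 table entries shared a gene symbol with another, and 0 pairs of libraries were identical. The protocol names ERCC spike-in RNA; spike-in counts were not analysed here, so all values are relative to the total RNA of each library.

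Total counts ran from 3219899 to 9267246 per library (median 6170915), and 16994 to 23757 genes had at least 1 count (median 20196). Counts are of PCR products without molecular identifiers, so counting intervals and floors cover counting error only. Where all libraries of a group had 0 counts of a gene, the fold difference was given as a lower bound against a floor of 3 counts over that group. Where a group had 1 to 3 counts in all, the ratio of counts was given with its exact 95% interval.

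Libraries were grouped by their labels into vector (Kir2.1, mutant Kir2.1, no AAV), sorted population and transduction. Titles number the libraries of a group as biological replicates, and libraries of different groups share numbers; no label ties a number to an animal, so p-values measure the spread between these libraries. Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling) in R 4.3.3, after filterByExpr with a minimum count of 10 and a minimum total of 15. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, with a threshold of 0.05, and all tests are two-sided. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. Comparisons within VIP nuclei shared 1 fit of 41 libraries, those within all nuclei 1 fit of 22, transduced neurons had a fit of 16, VIP against all nuclei 1 of 44, and the interaction of vector and population 1 of 35. Levels are counts scaled to the TMM-adjusted library size (CPM) within the fit of the sorted population, given as mean ± SD over libraries.

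The test was run on simulated counts with the real means and library sizes, in which 200 genes were changed by known folds. In the simulation of Kir2.1 against mutant in transduced VIP nuclei (20265 genes), 21% of genes changed 2-fold and 39% of those changed 4-fold were recovered, and 5 unchanged genes were called. For transduced neurons (15385 genes) the shares were 34% and 79% with 3 unchanged genes called. For non-transduced VIP nuclei (20280 genes) they were 18% and 51% with 10 called, and for all non-transduced nuclei (20208 genes) 24% and 57% with 5 called. Against 3 libraries without AAV, 33%, 31% and 30% of the genes changed 4-fold were recovered for non-transduced VIP, transduced VIP and all nuclei. For the interaction of vector and transduction (20279 genes) 13% and 45% were recovered and 25 unchanged genes called, and for that of vector and population (17697 genes) 4% and 47% with 5 called. No recovered gene had the wrong direction. A simulated 1.5-fold fall of the potassium channel list was called by camera (adjusted p = 3.5e-31) and by fry (adjusted p = 5.92e-16), with 0 of the other lists called. Simulated genes were drawn without correlation between them. In the real data that list had an estimated correlation of 0.17 in transduced VIP nuclei, so the simulation cannot tell how often correlated lists are called falsely.

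Gene lists were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, again with the correlation estimated from the data, and with fry; p-values were adjusted over the lists of a comparison with at least 5 measured members. The comparisons, groups, covariates, alternatives and 25 gene lists were fixed before the data were examined. The lists were immediate early genes, late activity-regulated genes, activity-regulated and growth factor genes of VIP cells, potassium channels, sodium, calcium and HCN channels, glutamate receptors, GABA receptor and inhibitory synapse genes, and markers of VIP neurons, all GABAergic neurons, excitatory neurons, other interneurons, astrocytes, oligodendrocytes, their precursors, microglia and vascular cells. They also held reactive glia genes, interferon and innate immune genes, p53 and DNA damage genes, unfolded protein and integrated stress response genes, mitochondrially encoded genes, cytosolic ribosomal proteins, nuclear oxidative phosphorylation genes, genes of the response to dissection and stress, and sex-linked genes, used only to read sex. Lists of sterol, neuropeptide, B and plasma cell, and T cell genes were written after the data had been seen. The pan-GABAergic list counts 12 table entries because Dlx6os1 has a pair of entries.

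Named genes followed a rule set with the comparisons. In each of the 4 comparisons of Kir2.1 with mutant these were the 8 risen and 8 fallen genes with the smallest p, up to 3 members past the threshold of each list, and 12 fixed activity and VIP genes (Fos, Fosb, Junb, Egr1, Nr4a1, Arc, Npas4, Bdnf, Nptx2, Igf1, Crh and Vip). Elsewhere they were the 5 risen and 5 fallen, and 1 member per list. Kcnj2 was reported in every comparison. Unnamed gene models, microRNA and small nucleolar RNA genes, Xist and Y-linked genes were skipped, and some genes that the rule names are not reported here. Fosb was below the count filter, as were Fos, Npas4, Nptx2, Crh and Vip in transduced neurons.

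Alternatives were other size factors, no count filter beyond 1 count, DESeq2 1.42.0, limma voom with sample weights, labelled sex as a covariate, a block of replicate numbers, a fit of the compared groups alone, and leaving out each library in turn. Fits and list tests without 6 libraries that stood apart from their group (correlation with the group's median profile under 0.87) and with sex read from expression were chosen after seeing the data. Xist and 4 Y-linked genes disagreed with the labelled sex in 32 of the 79 libraries. Each of 22 combinations of vector and replicate number had a single sex by expression, and 19 had a single labelled sex; all libraries without AAV were male by both. Counts of genes were set against 100 splits of the libraries into groups of the same sizes.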

Results

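Expression was measured in sorted nuclei of the adult mouse visual cortex, in 79 libraries. The mice carried Cre recombinase in neurons that express vasoactive intestinal peptide (VIP), a class of cortical GABAergic interneuron, together with the INTACT allele, which tags the nuclei of Cre-expressing cells for sorting. An AAV with the neuronal Syn1 promoter delivered either Kir2.1, an inwardly rectifying potassium channel that lowers neuronal excitability, or a mutant Kir2.1. Each vector also encoded the red fluorescent protein mScarlet with a KASH domain, which anchors proteins in the nuclear envelope. All libraries were labelled as 10 days dark housed, and the series asked how far activity that remains in the dark shapes expression. With Kir2.1 there were 10 libraries of transduced VIP nuclei, 10 of non-transduced VIP nuclei, 10 of all non-transduced nuclei and 8 of transduced neurons. With the mutant there were 9, 9, 9 and 8. Mice without AAV gave 3 libraries of VIP nuclei and 3 of all nuclei, all from males. Total counts ran from 3219899 to 9267246 per library. Transduced VIP libraries had 4265542 to 8239394 counts with Kir2.1 and 3530952 to 7010209 with the mutant, and transduced neurons 4731547 to 7614657 and 5126594 to 9267246. Non-transduced VIP libraries had 3219899 to 7517759 and 4392848 to 8252237, and all non-transduced nuclei 3261893 to 8784101 and 5487637 to 7275876. Libraries without AAV had 4751693 to 6215240 in VIP and 5547482 to 6243742 in all nuclei.

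Kcnj2 (ENSMUSG00000041695, mm10 chromosome 11, 111066164 to 111076821, plus strand), the gene that encodes Kir2.1, was higher in transduced than in non-transduced VIP nuclei with either vector. In VIP nuclei it was at 594 ± 233 CPM (SD, n = 10) with Kir2.1 and 764 ± 309 (n = 9) with the mutant when transduced, and at 15.2 ± 8.33 (n = 10) and 22.4 ± 8.03 (n = 9) when not. Transduced neurons had 532 ± 386 CPM with Kir2.1 and 406 ± 131 with the mutant (n = 8 each). All non-transduced nuclei had 34.6 ± 47.1 (n = 10; 21.0 ± 20.1 without Kir2.1 library 1, which was at 157 CPM, above transduced neuron library 10 at 142.9) and 16.3 ± 6.35 (n = 9), and nuclei of mice without AAV 6.95 ± 7.73 in VIP and 5.81 ± 1.82 in all nuclei (n = 3 each). The gain with transduction was 38.5-fold for Kir2.1 (log2 fold change 5.27 ± 0.39 SE, adjusted p = 3.64e-14) and 34.1-fold for the mutant (5.09 ± 0.41, adjusted p = 7.19e-13). Kcnj2 did not pass the test between vectors in transduced VIP nuclei (log2 fold change -0.36 ± 0.33, adjusted p = 0.808), transduced neurons (0.39 ± 0.32, adjusted p = 0.582), non-transduced VIP nuclei (-0.54, adjusted p = 0.699) or all non-transduced nuclei (1.09, adjusted p = 0.802). Gene counts do not separate the working channel, the mutant and the endogenous gene.

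Syne2 (ENSMUSG00000063450, chromosome 12, 75818134 to 76110926, plus strand), which encodes the KASH-domain protein nesprin-2, was the other gene to rise with transduction by either vector. It rose from 9.18 ± 6.21 to 94.5 ± 22.1 CPM with Kir2.1 (10.2-fold, adjusted p = 3.14e-08) and from 13.0 ± 6.75 to 132 ± 50.4 CPM with the mutant (10.1-fold, adjusted p = 2.22e-07). With the mutant vector, Kcnj2 and Syne2 were the 2 genes that rose with transduction and 0 fell (edgeR, 1110 genes at an unadjusted p under 0.05). A replicate block called more genes, as given with the processing.

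**Figure D1:**
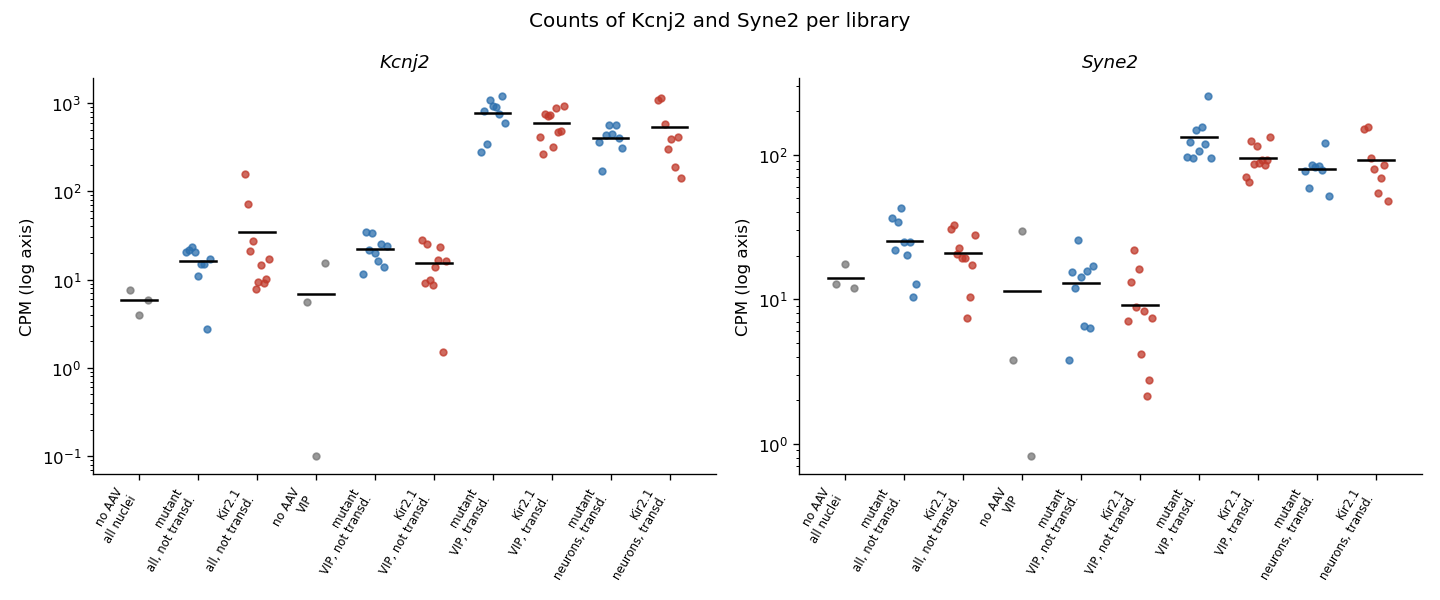
Kcnj2 and Syne2 in each library, in CPM on a log axis, by vector, sorted population and transduction; points are libraries, black lines are group means, and values under 0.1 are drawn at 0.1. Means of the transduced groups lie above those of non-transduced groups and mice without AAV, for Kcnj2 from 406 to 764 CPM against 5.81 to 34.6 CPM.

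Markers separated VIP nuclei from all nuclei in the 44 non-transduced libraries. Of 16 measured VIP neuron markers, 15 were higher and 1 lower in VIP nuclei, and all 12 entries of pan-GABAergic genes were higher. Vip itself had a log2 fold change of 10.14 ± 0.85 (SE) and Gad1, a GABA-synthesizing enzyme, 2.82 ± 0.19; Htr1f was the VIP marker that was lower (-2.86 ± 0.36). Of 20 excitatory markers 19 were lower, among them the vesicular glutamate transporter Slc17a7 (-3.86 ± 0.32). All 14 oligodendrocyte markers, 15 of 16 microglia markers (Csf1r -3.97 ± 0.37) and 6 of 10 precursor markers were lower. Among other interneuron markers 9 of 16 were lower (Sst -2.24 ± 0.41, Lamp5 -3.15 ± 0.30) and 3 higher (Elfn1, Npy and Kcnc2). Of astrocyte markers 3 were lower, 1 was higher and 11 did not pass, and 0 of 15 vascular markers passed. The marker counts adjusted over the list alone were the same, except for astrocytes (2 higher, 4 lower). In all, 2440 genes were higher and 3826 lower in VIP nuclei of 22855 tested (edgeR). Kcnj2 did not pass (-0.08, adjusted p = 0.961).

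The comparison of Kir2.1 with the mutant in transduced VIP nuclei asked how the working channel changed these cells in the dark. Some activity-regulated genes, neuropeptides and markers of VIP and GABAergic neurons were lower with Kir2.1, though most members of each such list did not pass. Genes of sterol synthesis and uptake were among the strongest rises. Of 21207 genes, 75 rose and 219 fell (edgeR, adjusted p under 0.05), 56 and 133 of them by at least 2-fold. Mlip (ENSMUSG00000032355, chromosome 9, 77102081 to 77352969, minus strand), a gene named for its interaction with lamin A, fell from 161 ± 25.3 CPM (SD, n = 9) to 37.4 ± 19.1 (n = 10), a log2 fold change of -2.11 ± 0.21 (SE, adjusted p = 1.36e-09). Pde10a (ENSMUSG00000023868, chromosome 17, 8525372 to 8986648, plus strand), a cyclic nucleotide phosphodiesterase, fell from 707 ± 186 to 169.7 ± 70.3 CPM (-2.06 ± 0.23, adjusted p = 2.88e-08). Npy (ENSMUSG00000029819, chromosome 6, 49822710 to 49829507, plus strand), which encodes neuropeptide Y, fell from 188 ± 92.4 to 18.7 ± 10.8 CPM (-3.33 ± 0.41, adjusted p = 4.37e-07). The receptor kinase Egfr fell 2.91-fold, the long noncoding RNA Dlx6os1 2.95-fold, Cnmd 15.4-fold (23.5-fold without Kir2.1 library 2), the thyroid hormone receptor Thrb 2.14-fold and the cation channel Trpc6 3.09-fold (adjusted p from 2.1e-08 to 2.05e-06). Camk2a (ENSMUSG00000024617, chromosome 18, 60925618 to 60988152, plus strand), a subunit of CaM kinase II, rose from 535 ± 49.2 to 990.2 ± 169 CPM (0.89 ± 0.12, adjusted p = 1.52e-06). Fdps (ENSMUSG00000059743, chromosome 3, 89093588 to 89101959, minus strand), which makes farnesyl diphosphate, rose from 18.1 ± 6.97 to 68.8 ± 16.9 CPM (1.92 ± 0.27, adjusted p = 3.3e-06). The sterol synthesis gene Msmo1 rose 3.07-fold. Fbln2 (2.25-fold), Pik3ip1 (3.06-fold), Socs2 (1.85-fold) and Pcyt2 (2.51-fold) were other leading rises, with adjusted p from 5.73e-06 to 0.00013.

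Of 25 measured immediate early genes, the first to be transcribed after neuronal firing, 5 fell, 0 rose and 20 did not pass. When adjusted over the list alone 8 fell (camera adjusted p = 3.76e-09, and 0.00202 with an estimated correlation). Nr4a1 (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795, plus strand), a nuclear receptor, fell from 33.7 ± 16.9 to 4.63 ± 3.47 CPM (7.25-fold, adjusted p = 3.3e-06). Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273, plus strand) fell from 18.04 ± 10.5 to 0.883 ± 2.05 CPM (19.5-fold, adjusted p = 0.00385). Kir2.1 library 3 was at 6.55 CPM, and without it the fall was 66-fold (adjusted p = 4.55e-05). Npas4 (ENSMUSG00000045903, chromosome 19, 4984355 to 4990316, minus strand), an activity-dependent transcription factor, had 2 counts over the Kir2.1 group, both in library 2, and 193 over the mutant group, a depth-adjusted ratio of 134 with a 95% counting interval of 36.6 to 1120 (adjusted p = 0.00115). Egr1 (-0.99, adjusted p = 0.557), Nptx2 (-1.01, adjusted p = 0.845), Bdnf (-0.99, adjusted p = 0.887), Junb (-0.43, adjusted p = 0.891) and Arc (0.47, adjusted p = 0.956) did not pass.

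Of 28 late activity-regulated genes 4 fell and 24 did not pass, also 4 when adjusted over the list alone (camera adjusted p = 9.45e-09, and 2.65e-05 with an estimated correlation). They included the secretory granule gene Vgf (11.6-fold lower, 30.7 ± 14.9 to 2.59 ± 3.17 CPM), the prohormone convertase Pcsk1 (ENSMUSG00000021587, chromosome 13, 75089826 to 75134861, plus strand; 2.64-fold lower, adjusted p = 4.79e-06) and Pthlh (3.25-fold lower). Of 21 activity-regulated and growth factor genes of VIP cells 8 fell, 1 rose and 12 did not pass, with 8 fallen and 2 risen when adjusted over the list alone (camera adjusted p = 9.61e-08, and 0.000121 with an estimated correlation). Penk (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819, minus strand), the enkephalin precursor, fell from 556 ± 280 to 135 ± 63.5 CPM (adjusted p = 1.03e-05), and Crh, corticotropin-releasing hormone, from 140.1 ± 89.7 to 23.2 ± 17.7 CPM (adjusted p = 0.000104). Igf1, a growth factor, fell 1.59-fold (543 ± 83.6 to 342 ± 80.7 CPM, adjusted p = 0.00177).

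**Figure D2:**
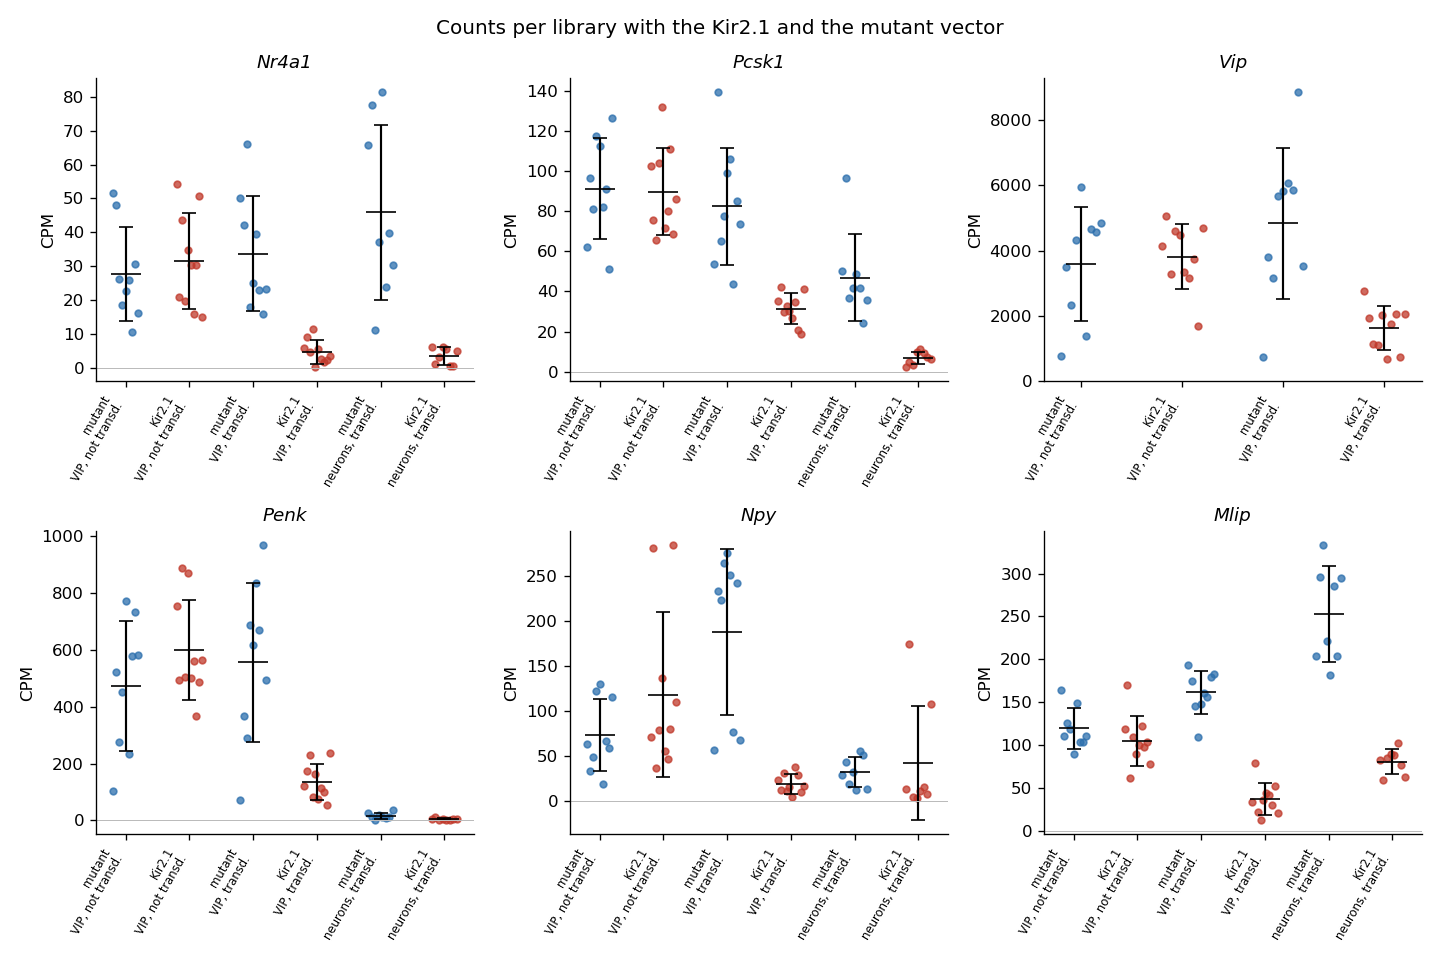
CPM per library of Nr4a1, Pcsk1, Vip, Penk, Npy and Mlip by group; points are libraries and bars are mean ± SD. In transduced VIP nuclei the Kir2.1 mean lies below the mutant mean in all 6 panels, for example 4.63 against 33.7 CPM for Nr4a1 and 18.7 against 188 CPM for Npy.

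Of 16 VIP neuron markers 4 fell and 12 did not pass. Adjusted over the list alone 5 fell and 2 rose (camera adjusted p = 0.000121, and 0.00959 with an estimated correlation). Vip (ENSMUSG00000019772, chromosome 10, 5639218 to 5647617, plus strand) fell from 4839 ± 2318 to 1627 ± 679 CPM (log2 fold change -1.57 ± 0.29, adjusted p = 0.00046), and the RNA-editing family member Adarb2 fell 1.95-fold. Of 12 pan-GABAergic entries 2 fell and 10 did not pass, 6 falling when adjusted over the list alone (camera adjusted p = 5.5e-08, and 0.00092 with an estimated correlation). Besides Dlx6os1 the transcription factor Dlx1 fell 2.43-fold. Of 15 other interneuron markers 2 fell, Npy and the potassium channel Kcnc2 (1.56-fold), and 4 when adjusted over the list alone (camera adjusted p = 0.0416, and adjusted p = 0.151 with an estimated correlation). Libraries that stood apart from their group were found on both sides: Kir2.1 libraries 1 and 6 and mutant library 1 had correlations of 0.831, 0.854 and 0.847 with their group's median profile. Without the libraries that stand apart 6 pan-GABAergic entries fell, and other interneuron markers did not pass camera (adjusted p = 0.0815).

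Of 40 potassium channel genes 4 fell, 1 rose and 35 did not pass, with 8 falling and 1 rising when adjusted over the list alone (camera adjusted p = 0.000121, but adjusted p = 0.258 with an estimated correlation). Kcnc1, a fast-spiking delayed rectifier, rose 2.02-fold (adjusted p = 0.000365), and Kcnn2 and Kcnj3 fell 1.64-fold and 1.72-fold. Of 33 sodium, calcium and HCN channel genes 2 fell, among them Fgf13 (1.73-fold), and also 2 when adjusted over the list alone (camera adjusted p = 0.0113, but adjusted p = 0.557 with an estimated correlation). Of 21 GABA receptor and inhibitory synapse genes 1 fell, Gabrb2 (1.82-fold), with 2 when adjusted over the list alone (camera adjusted p = 0.016, but adjusted p = 0.153 with an estimated correlation). Of 26 glutamate receptor genes 1 fell, Grin2a (1.77-fold), with 4 when adjusted over the list alone (camera adjusted p = 0.0689). Without the libraries that stand apart glutamate receptors passed (0.0051), but not with an estimated correlation (adjusted p = 0.357). Cytosolic ribosomal proteins had 0 of 37 genes past the threshold, also adjusted over the list alone, and a median log2 fold change of 0.34 (camera adjusted p = 0.000112, but adjusted p = 0.607 with an estimated correlation).

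The other lists did not pass in transduced VIP nuclei. Markers of oligodendrocytes (14 measured), their precursors (6), microglia (16) and vascular cells (13) had 0 genes past the threshold, also adjusted over the list alone, with camera adjusted p from 0.39 to 0.921. Of 20 excitatory markers 1 rose, Camk2a, with 2 risen and 1 fallen when adjusted over the list alone (adjusted p = 0.198). Of 15 astrocyte markers 1 fell, the bicarbonate transporter Slc4a4 (1.9-fold), and of 15 reactive glia genes 1, Cp (2.36-fold); both counts were the same adjusted over the list alone (adjusted p = 0.406 each), and the reactive glia median of 0.12 had the opposite sign to its test. Interferon and innate immune (24), p53 (16), unfolded protein response (26), mitochondrially encoded (9), nuclear oxidative phosphorylation (27) and dissection response genes (12) had 0 past the threshold, also adjusted over the list alone (adjusted p from 0.198 to 0.406). The call of Fgf13 ended without any 1 of Kir2.1 libraries 3, 5 or 10 and mutant libraries 1, 7 or 9 (adjusted p up to 0.0635).

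In transduced neurons, late activity-regulated genes, activity-regulated genes of VIP cells, and markers of GABAergic and VIP neurons were lower as lists with Kir2.1 than with the mutant, with either correlation, though most members of each did not pass. Immediate early, channel and receptor gene lists were lower with the preset correlation and did not pass with an estimated one (adjusted p from 0.112 to 0.3). Without Kir2.1 library 10, which stood apart from its group (correlation 0.862), VIP markers did not pass with an estimated correlation (adjusted p = 0.0937). Of 15949 genes tested, 347 rose and 551 fell, 156 and 243 of them by at least 2-fold (edgeR, n = 8 against 8). DESeq2 called 1382, and a replicate block across vectors called fewer, as given with the processing. Nos1 (ENSMUSG00000029361, chromosome 5, 117781032 to 117958840, plus strand), the neuronal nitric oxide synthase, rose from 11.2 ± 6.10 to 94.0 ± 22.3 CPM (log2 fold change 3.08 ± 0.28, adjusted p = 2.65e-07). Cpne6 rose 3.39-fold, Echdc2 4.36-fold, Matn2 2.99-fold, the imprinted gene Nnat 5.47-fold, Rogdi 2.72-fold, Zfhx2 3.06-fold and Rnf207 4.08-fold. R3hdm1 (ENSMUSG00000056211, chromosome 1, 128103301 to 128237736, plus strand) fell from 1456 ± 179 to 607 ± 59.9 CPM (-1.26 ± 0.12, adjusted p = 2.65e-07). Mlip fell from 253 ± 56.1 to 80.9 ± 14.1 CPM (-1.64 ± 0.16, adjusted p = 2.65e-07). The metabotropic glutamate receptor Grm3 fell 3.71-fold, Osbpl3 2.88-fold, Trhde, which degrades thyrotropin-releasing hormone, 3.74-fold, the transcription factor Bach2 3.75-fold, Samd4 6.16-fold and Zfp804b 5.59-fold. All 16 of these leading genes had an adjusted p of 3.51e-05 or smaller.

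Of 17 immediate early genes measured in neurons 2 fell and 15 did not pass, with 5 falling when adjusted over the list alone (camera adjusted p = 3.32e-05, but adjusted p = 0.112 with an estimated correlation). Nr4a1 fell from 45.9 ± 25.9 to 3.53 ± 2.57 CPM (log2 fold change -3.70 ± 0.48, adjusted p = 1.7e-05) and Egr1 from 43.1 ± 18.2 to 4.38 ± 3.60 CPM (-3.28 ± 0.46, adjusted p = 4.63e-05). Of 25 late activity-regulated genes 9 fell, 1 rose and 15 did not pass, with 13 falling and 1 rising when adjusted over the list alone (camera adjusted p = 1.67e-08, and 0.034 with an estimated correlation). Pcsk1 fell from 46.9 ± 21.6 to 6.75 ± 3.14 CPM, the synaptic scaffold Homer1 fell 2.19-fold, the granule protein Scg2 2.59-fold, and Bdnf, a neurotrophin, from 22.6 ± 12.1 to 4.02 ± 3.52 CPM (adjusted p = 0.0111). Of 16 activity-regulated and growth factor genes of VIP cells 5 fell and 11 did not pass, with 10 falling when adjusted over the list alone (camera adjusted p = 1e-08, and 0.000227 with an estimated correlation). Arc (-1.85 ± 0.69, adjusted p = 0.123), Igf1 (-0.74, adjusted p = 0.558) and Junb (-0.10, adjusted p = 0.928) did not pass. Arc passed without Kir2.1 library 4 (adjusted p = 0.0461), without the count filter (0.0411) and with limma voom (0.0328); another normalization, DESeq2, either sex covariate and leaving out the libraries that stand apart gave 0.115 to 0.2.

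Markers of GABAergic neurons moved with the vector in this sort. Whether the share of interneuron nuclei or their expression changed was not tested. Of 8 measured pan-GABAergic entries 3 fell, 0 rose and 5 did not pass, with 5 falling when adjusted over the list alone (camera adjusted p = 2.96e-06, and 0.034 with an estimated correlation). Among them were Dlx6os1 (23.7 ± 8.98 to 3.88 ± 4.42 CPM; 9.86-fold without Kir2.1 library 10) and Gad1 (72.9 ± 21.4 to 37.6 ± 11.1 CPM). Of 6 VIP markers 2 fell, Adarb2 (4.38-fold) and Htr1f (2.08-fold), with 3 when adjusted over the list alone (camera adjusted p = 0.0017, and 0.0413 with an estimated correlation). Htr1f was the list member that was lower in VIP than in all nuclei, and Vip itself was below the count filter in neurons. Of 14 other interneuron markers 2 fell, Reln (2.42-fold) and Lamp5 (1.9-fold), and 1 rose, Nos1, the same counts as adjusted over the list alone (camera adjusted p = 0.389). Of 20 excitatory markers 1 rose, Nptx1 (1.8-fold), and 1 fell, Rasgrf2 (1.67-fold), with 1 and 5 when adjusted over the list alone (camera adjusted p = 0.0489, and adjusted p = 0.0752 without library 10, but adjusted p = 0.174 with an estimated correlation). Of 13 astrocyte markers 3 fell, the glutamate transporter Slc1a2 (1.98-fold), Slc4a4 (1.7-fold) and Aldh1l1 (3.36-fold), with 3 falling and 1 rising when adjusted over the list alone (camera adjusted p = 0.0881).

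Of 39 potassium channel genes in neurons 11 fell, 1 rose and 27 did not pass, with 14 falling and 1 rising when adjusted over the list alone (camera adjusted p = 3.35e-06, but adjusted p = 0.112 with an estimated correlation). The calcium-activated channel Kcnma1 fell 1.66-fold, Kcnab1 1.84-fold and Kcnip4 1.8-fold. Of 32 sodium, calcium and HCN channel genes 7 fell and 1 rose, with 10 and 1 when adjusted over the list alone (camera adjusted p = 0.000447, but adjusted p = 0.288 with an estimated correlation), including Fgf13 (3.76-fold) and Cacnb4 (1.58-fold). Of 25 glutamate receptor genes 7 fell and 1 rose, with 10 and 2 when adjusted over the list alone (camera adjusted p = 0.0017, but adjusted p = 0.3 with an estimated correlation), including Grm3, Grik1 (2.85-fold) and Gria3 (1.63-fold). Of 21 GABA receptor and inhibitory synapse genes 3 fell, Gabra4 (2.29-fold), Gabrg3 (1.84-fold) and Gabrb2 (1.48-fold), with 6 when adjusted over the list alone (camera adjusted p = 0.000395, but adjusted p = 0.112 with an estimated correlation). Of 9 mitochondrially encoded genes mt-Nd1 fell 1.57-fold, also adjusted over the list alone (camera adjusted p = 0.00833, but adjusted p = 0.479 with an estimated correlation). Of 37 cytosolic ribosomal proteins Rpl6 rose 1.67-fold, with 0 when adjusted over the list alone (camera adjusted p = 0.00398, and adjusted p = 0.0705 without library 10, but adjusted p = 0.598 with an estimated correlation).

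Of 18 interferon and innate immune genes 1 rose in neurons, Stat2 (2.16-fold), also adjusted over the list alone (camera adjusted p = 0.0986). Oligodendrocyte markers (9), microglia markers (8), reactive glia (10), p53 (14), unfolded protein response (21), oxidative phosphorylation (27) and dissection response genes (9) had 0 past the threshold, also adjusted over the list alone (camera adjusted p from 0.237 to 0.906). The medians of reactive glia and p53 genes, within 0.03 of 0, had the opposite sign to their tests. Leaving out 1 library ended the calls of Gabrb2 (Kir2.1 3, 4, 5 or 9, mutant 3, 4 or 9; adjusted p up to 0.0663) and mt-Nd1 (Kir2.1 3, 4, 5 or 8, mutant 2, 4, 5, 7 or 9; 0.0851). The same held for Rpl6 (Kir2.1 4, 7 or 10, mutant 2, 3, 4, 6, 7 or 9; 0.0921), Aldh1l1 (mutant 3, 7 or 9; 0.0721) and Lamp5 (mutant 5 or 7; 0.0541).

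The responses of transduced VIP nuclei and transduced neurons overlapped. Among 15763 genes tested in both, 18 rose in both, against 1.37 for independent lists of 63 and 344 genes, and 70 fell in both, against 6.04 for lists of 175 and 544. They included Mlip, Nr4a1, Pcsk1, Adarb2 and Dlx6os1. In neurons the latter pair fell beside pan-GABAergic entries, of which all 8 were negative (median log2 fold change -1.01). In 4 genes, chosen for mention after their values were seen, the directions were opposite: Cdh13 (-1.08 in VIP nuclei, 0.97 in neurons), Clstn2 (-1.08 and 0.48), Galnt14 (-0.54 and 1.01) and Nrep (0.998 and -0.81). Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.358. The highest of the other splits among 100 that kept replicate numbers together gave 0.272. No library was shared, but libraries with the same number may share an animal.

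**Figure D3:**
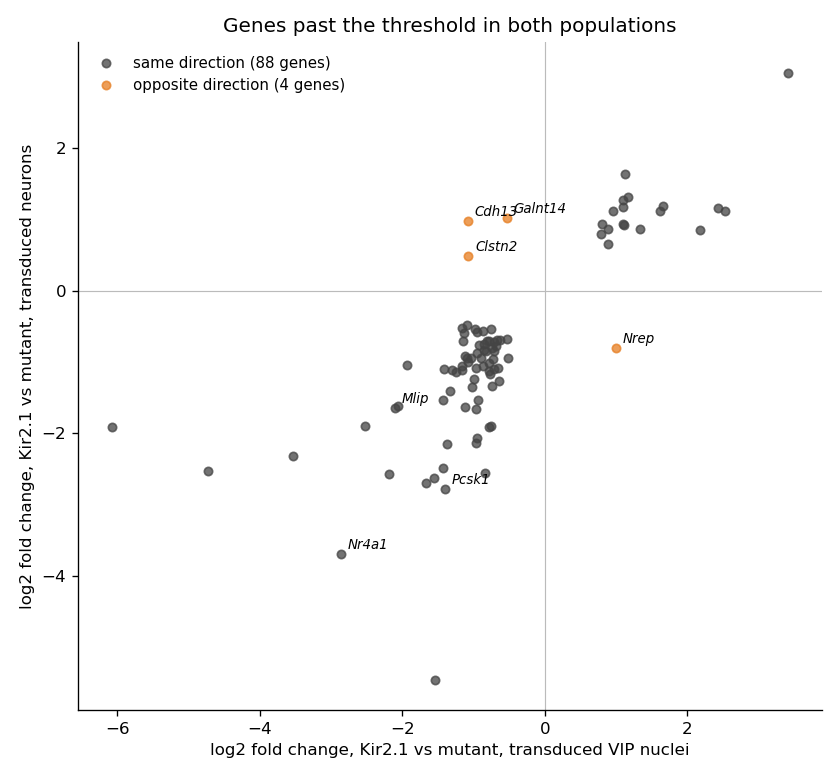
Log2 fold change of Kir2.1 against mutant in transduced VIP nuclei (x axis) and in transduced neurons (y axis) for the genes past the threshold in both; each point is a gene. Most points lie in the lower left (70 genes fell in both) or upper right (18 rose in both), and 4 had opposite directions.

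Tested directly, the log2 fold change of Kir2.1 against mutant differed between VIP nuclei and neurons in 58 genes (37 higher and 21 lower in VIP nuclei, of 18359 tested, edgeR). The count was 274 without the count filter and 104 with DESeq2. It fell to 38, 38 and 36 without Kir2.1 neuron libraries 3, 4 and 9, and to 38 without mutant neuron library 3. R3hdm1, which fell in neurons, was at 305 ± 47.3 CPM with Kir2.1 and 350.4 ± 47.5 with the mutant in VIP nuclei (difference of log2 fold changes 1.10 ± 0.17, adjusted p = 0.000328). Egfr (4.01 ± 0.61, adjusted p = 0.000328) was low in neurons, at 0.211 ± 0.372 CPM with Kir2.1 and 9.20 ± 5.87 with the mutant. The interneuron transcription factor Prox1 (3.04 ± 0.57) was likewise at 0.588 ± 1.09 and 4.11 ± 1.97 CPM in neurons. The neuron sort held several cell types, and its pan-GABAergic entries were lower with Kir2.1. A different response and a different share of interneuron nuclei in that sort therefore cannot be told apart here. The differences of Grik1 (1.91), Sidt1 (0.99), Cldn1 (5.62), Gabra4 (1.37) and Camk2a (0.88) also pointed upward. The adhesion gene Cdh13 (-2.02 ± 0.29, adjusted p = 0.000194), Clstn2 (-1.53), Trpc6 (-1.76), Galnt14 (-1.51), Hs3st4 (-2.34) and Npy (-3.68) pointed downward. Kcnj2 did not pass (-0.71, adjusted p = 0.899), and Npy did not pass without Kir2.1 neuron library 4 (-2.86, adjusted p = 0.066). Without 1 Kir2.1 neuron library Egfr was at 4.92 (library 10), Cldn1 at 6.56 (library 3) and Prox1 at 3.76 or 3.86 (library 6 or 8).

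Non-transduced nuclei were compared to ask whether cells without the vector differed between mice injected with Kir2.1 and with the mutant. In non-transduced VIP nuclei 0 of 21207 genes passed (edgeR, smallest adjusted p = 0.253, 1843 at an unadjusted p under 0.05; 6 with DESeq2, 0 with limma voom). In all non-transduced nuclei 0 of 21362 passed (smallest adjusted p = 0.521, 1289 at an unadjusted p under 0.05; 2 with DESeq2, 0 with limma voom). Vip was at 3817 ± 996 CPM (n = 10) with Kir2.1 and 3595 ± 1743 (n = 9) with the mutant in non-transduced VIP nuclei (log2 fold change 0.09 ± 0.29, adjusted p = 0.974). Nr4a1 was at 31.6 ± 14.3 and 27.8 ± 13.9 CPM (0.18 ± 0.37, adjusted p = 0.948), and Igf1 at 462 ± 93.3 and 486 ± 61.4 CPM (-0.07, adjusted p = 0.941). Arc (2.45, adjusted p = 0.525), Bdnf (-2.13, adjusted p = 0.663), Junb (0.87, adjusted p = 0.708), Crh (-0.58, adjusted p = 0.755), Npas4 (-0.72, adjusted p = 0.914), Fos (0.41, adjusted p = 0.945), Nptx2 (0.36, adjusted p = 0.968) and Egr1 (0.05, adjusted p = 0.997) did not pass either. In all non-transduced nuclei Egr1 was at -1.001 ± 0.41 (adjusted p = 0.768), Nptx2 at -1.72 (0.822) and Npas4 at -1.40 (0.895). There Bdnf was at -0.50 (0.894), Igf1 at -0.60 (0.958), Nr4a1 at -0.30 (0.958), Junb at -0.41 (0.962), Fos at 0.41 (0.984), Crh at -0.55 (0.992), Vip at 0.23 (0.997) and Arc at 0.02 (0.999).

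In non-transduced VIP nuclei 6 of 24 lists passed camera with the preset correlation and 0 with an estimated one. All 37 cytosolic ribosomal protein genes and all 27 nuclear oxidative phosphorylation genes had positive log2 fold changes, with medians of 0.64 and 0.50. In these lists 17 and 9 genes rose when adjusted over the list alone (camera adjusted p = 1.29e-19 and 1e-11, but adjusted p = 0.287 each with an estimated correlation). Kir2.1 library 9 stood apart from its group (correlation 0.796 with the median profile). Ribosomal protein genes held 0.375% of counts in it and 0.104% to 0.265% in the other Kir2.1 libraries. They held 0.0331% in mutant library 1 (correlation 0.859) and 0.0511% to 0.185% in the other mutant libraries. Without the libraries that stand apart the medians were 0.32 and 0.21, and 0 members of either list rose when adjusted over the list alone (camera adjusted p = 7.86e-08 and 6.18e-05, but adjusted p = 0.469 each with an estimated correlation). Potassium channels, sodium, calcium and HCN channels, glutamate receptors and inhibitory synapse genes pointed downward (camera adjusted p from 7.25e-05 to 0.0045, but adjusted p from 0.185 to 0.523 with an estimated correlation). In all non-transduced nuclei 4 of 24 lists passed and 0 with an estimated correlation. Immediate early genes (median -0.46) and potassium channels (median -0.18) pointed downward, and ribosomal and oxidative phosphorylation genes upward (camera adjusted p from 6.23e-05 to 0.000422, but adjusted p from 0.532 to 0.715 with an estimated correlation); 0 of their members passed when adjusted over the list alone.

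Within VIP nuclei of mice injected with Kir2.1, some activity-regulated, neuropeptide and GABAergic genes were lower in transduced than in non-transduced nuclei, though most members of each such list did not pass. Of 21207 genes, 36 rose and 127 fell (edgeR, n = 10 against 10), 163 in all, against 105 in a fit of the compared groups alone. Pcsk1 fell from 89.7 ± 21.9 to 31.3 ± 7.68 CPM (2.87-fold, adjusted p = 8.44e-07), Nr4a1 from 31.6 ± 14.3 to 4.63 ± 3.47 CPM (6.81-fold, adjusted p = 6.69e-06), Npy 6.28-fold and Vip from 3817 ± 996 to 1627 ± 679 CPM (2.35-fold, adjusted p = 0.0154). Cnmd fell 20.4-fold (30.8-fold without transduced library 2), Dlx6os1 3.12-fold, Egfr 2.62-fold, Pde10a 3.5-fold, Pthlh 2.4-fold and Cp 2.13-fold, and Fos 12.4-fold (adjusted p = 0.026), or 41.6-fold without transduced library 3 (adjusted p = 0.000331). Npas4 had 2 counts over the transduced group, both in library 2, and 111 over the non-transduced group, a ratio of 62.3 (95% counting interval 16.9 to 521). Besides Kcnj2 and Syne2, Camk2a (1.61-fold), Fbln2 (1.98-fold), Kcnc1 (2-fold), BC030499 (5.65-fold) and the class I histocompatibility gene H2-K1 (4.08-fold, 27.2 ± 27.2 to 109.9 ± 80.0 CPM) rose. With the mutant, H2-K1 also lay higher in transduced libraries (18.2 to 159.9 CPM before TMM scaling) than in non-transduced ones (1.648 to 41.74), but did not pass. Fgf13 (1.75-fold) and Gabrb2 (1.5-fold) fell, and Ly6c1, a vascular marker, had 0 counts in all 10 transduced libraries. It had counts in 2 of the 10 non-transduced ones, libraries 7 (46.9 CPM) and 8 (1.99 CPM), so its bound of at least 110-fold lower rested on library 7 and was at least 4.95-fold without it.

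Immediate early genes fell in 4 of 25 members with transduction by Kir2.1 (6 adjusted over the list alone; camera adjusted p = 2.72e-07, and 0.009 with an estimated correlation), and late activity-regulated genes in 3 of 28 (3 fallen and 1 risen adjusted over the list alone; 0.000176, and 0.00243 with an estimated correlation). Activity-regulated genes of VIP cells fell in 4 and rose in 1 of 21 (8 and 2 adjusted over the list alone; 5.56e-07, and 0.000472 with an estimated correlation), and pan-GABAergic entries fell in 2 of 12 (4 adjusted over the list alone; 2.72e-07, and 0.00187 with an estimated correlation). VIP markers fell in 3 of 16 (5 fallen and 1 risen adjusted over the list alone; camera adjusted p = 0.00566, but adjusted p = 0.0681 with an estimated correlation) and other interneuron markers in 2 of 15, also 2 adjusted over the list alone (camera adjusted p = 0.0159, but adjusted p = 0.0681 with an estimated correlation). Interferon and innate immune genes rose in 1 of 24 (2 adjusted over the list alone; camera adjusted p = 0.000176, but adjusted p = 0.0702 with an estimated correlation). All 9 mitochondrially encoded genes had negative log2 fold changes, with 0 past the threshold and 1 adjusted over the list alone (camera adjusted p = 0.000353, but adjusted p = 0.303 with an estimated correlation). Without the libraries that stand apart VIP markers passed with an estimated correlation (adjusted p = 0.00848), and other interneuron markers did not pass with the preset one (0.121). Potassium channels, sodium, calcium and HCN channels and glutamate receptors then passed with it, downward (0.000965 to 0.0384, but adjusted p from 0.268 to 0.423 with an estimated correlation). Leaving out 1 library ended the call of Ly6c1 (any transduced library, adjusted p up to 0.0682; without non-transduced 7 or 8 it was below the count filter and had no test), of H2-K1 (transduced 2 or 10, 0.0592), of Fos (non-transduced 3, 0.052) and of Fgf13 (transduced 3, 5 or 10, non-transduced 6 or 8, 0.0741). The call of Gabrb2 ended without each of the 20 libraries (up to 0.0859) except transduced 6 and non-transduced 1, 3, 5 and 10.

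With the mutant vector, interferon and innate immune genes were the only planned list that passed with either correlation between transduced and non-transduced VIP nuclei. They had a median log2 fold change of 1.02, with 0 of 24 past the threshold and 3 risen when adjusted over the list alone (camera adjusted p = 2.09e-08, and 0.0205 with an estimated correlation). Without the libraries that stand apart they did not pass with an estimated correlation (adjusted p = 0.0688). Immediate early genes (median 0.48), ribosomal and oxidative phosphorylation genes pointed upward and glutamate receptors downward (camera adjusted p from 3.17e-06 to 0.0369, but adjusted p from 0.445 to 0.699 with an estimated correlation).

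The interaction of vector and transduction in VIP nuclei tested whether the effect of transduction differed between Kir2.1 and the mutant. It did in 85 genes, 26 with a higher and 59 with a lower effect with Kir2.1 (edgeR, 21207 tested). Without the count filter the count was 719. It fell to 52 and 48 without transduced mutant libraries 2 and 4, and to 50 and 52 without non-transduced mutant libraries 3 and 7. In simulation this test called 25 unchanged genes, so a share of the 85 may be false. Npy had the smallest p of the downward genes (difference of log2 fold changes -4.02 ± 0.56, adjusted p = 3.06e-05), followed by Mlip (-1.93), Pde10a (-1.96), Cnmd (-4.04, or -4.65 without transduced Kir2.1 library 2) and Egfr (-1.40). Nr4a1 (-3.04 ± 0.54, adjusted p = 0.00151), Pthlh (-1.81), Penk (-2.39), Dlx6os1 (-1.64) and Vip (-1.66 ± 0.41, adjusted p = 0.0432) were also lower. Fbln2 (1.36), Kcnc1 (1.44), Fdps (1.73) and Socs2 (0.98) were higher, as was Ndp, which had 0 counts in all 9 transduced mutant libraries and means of 2.19 CPM in transduced and 0.0198 CPM in non-transduced Kir2.1 libraries. With a replicate block within a vector Ndp did not pass (adjusted p = 0.463). Kcnj2 did not pass (0.18, adjusted p = 1). Immediate early (1 of 25 lower), late activity-regulated (3 of 28), VIP-cell activity-regulated (3 of 21), VIP marker (2 of 16) and pan-GABAergic genes (2 of 12) pointed downward, with 5, 3, 6, 4 and 4 lower and 0, 0, 1, 0 and 0 higher when adjusted over the list alone (camera adjusted p from 1.02e-08 to 0.000278, and 0.00287 to 0.02 with an estimated correlation). Other interneuron markers, ribosomal and oxidative phosphorylation genes passed with the preset correlation (camera adjusted p from 7.25e-05 to 0.02, but adjusted p from 0.0774 to 0.873 with an estimated correlation). Of these lists other interneuron markers (0.171) and ribosomal genes (0.579) did not pass without the libraries that stand apart. The call of Vip ended with labelled sex (adjusted p = 0.0545) or sex by expression (0.0534) as a covariate, against 0.000837 to 0.0446 with another normalization, no count filter, DESeq2 or without the libraries that stand apart, and without each of 23 of the 38 libraries (up to 0.079). It held without Kir2.1 transduced 1, 2, 5, 8 or 10, Kir2.1 non-transduced 3, 7 or 9, mutant transduced 1, 3 or 9, and mutant non-transduced 1, 4, 5 or 8.

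Nuclei of mice injected with the mutant vector were compared with those of mice without AAV, to see what injection itself brought. In all non-transduced nuclei 45 genes rose and 3 fell of 21362 (edgeR, n = 9 against 3), and DESeq2 called 333. Complement and class I histocompatibility genes were among the rises with the smallest p. The complement gene C4b was at least 122-fold higher and the class I histocompatibility genes H2-Q7 and H2-Q6 at least 98.6-fold and 132-fold higher, since the 3 libraries without AAV had 0 counts. H2-K1 rose from 4.98 ± 4.32 to 139 ± 79.6 CPM (27.9-fold, adjusted p = 7e-04; 18.5-fold without library 2 of the mice without AAV) and the thromboxane synthase Tbxas1 23-fold (adjusted p = 0.000648). Of 25 interferon and innate immune genes 4 rose, with 6 when adjusted over the list alone, and their median was 2.77, or 2.34 with 6 genes at 0 without AAV set to their bounds (camera adjusted p = 3.15e-10, but adjusted p = 0.206 with an estimated correlation). Of 16 microglia markers 0 passed, 3 rose when adjusted over the list alone, and the median was 0.49 (camera adjusted p = 6.76e-06, but adjusted p = 0.382 with an estimated correlation). Potassium channels pointed upward, and unfolded protein response, ribosomal, oxidative phosphorylation, pan-GABAergic and other interneuron genes downward (camera adjusted p from 1.36e-11 to 0.0279, but adjusted p from 0.206 to 0.414 with an estimated correlation). Glt8d2 fell 2.77-fold, the synaptic adhesion gene Lrrtm1 2.59-fold, and Copz2, with 0 counts in the 9 injected libraries, was at least 188-fold lower. These 3 falls did not pass without library 2 of the mice without AAV (adjusted p up to 0.389), Lrrtm1 also without library 1 of them or mutant library 2 or 3, and the count of 48 genes fell to 21 without that library 2. With labelled sex or sex by expression as a covariate, Copz2 (adjusted p = 0.0501 and 0.0998) and Lrrtm1 (0.0507 and 0.107) did not pass. The median log2 fold change of all genes was 0.11.

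In VIP nuclei 0 genes passed between non-transduced mutant libraries and those without AAV in edgeR (smallest adjusted p = 0.0593), and 48 with DESeq2. The median log2 fold change was 0.12, and 2709 genes had an unadjusted edgeR p under 0.05, against 1060 by chance. Other settings called 2 to 8 genes, and leaving out library 1 of the mice without AAV 1 gene, while another normalization called 0. Transduced mutant VIP nuclei had 6 genes higher and 0 lower than VIP nuclei without AAV (edgeR, 1969 at an unadjusted p under 0.05). DESeq2 called 63 genes, and a fit of the compared groups alone 11. Kcnj2 (109-fold, adjusted p = 5.74e-08; 72.3-fold and 283-fold without libraries 2 and 3 of mice without AAV), Syne2 (11.5-fold, adjusted p = 0.0118; 58-fold without library 2) and the immunoglobulin light chain Igkc (43.5 ± 25.5 against 0.274 ± 0.474 CPM, the latter from library 3 alone, adjusted p = 0.0204) were among them. AC148019.2 had 1 count without AAV, in library 3, and 438 with the mutant, a ratio of 161 (95% counting interval 28.7 to 6360). Kcnj2 did not pass in non-transduced nuclei against those without AAV (1.68, adjusted p = 0.278 in VIP, and 1.48, adjusted p = 0.425 in all nuclei). In non-transduced VIP nuclei 7 of the planned lists passed camera and in transduced ones 8, 0 of either with an estimated correlation (adjusted p from 0.127 to 0.42 and from 0.175 to 0.547), among them immediate early genes in transduced nuclei (camera adjusted p = 0.000626, but adjusted p = 0.175 with an estimated correlation). The count of 6 fell to 2, 3 and 1 without libraries 1, 2 and 3 of mice without AAV. The call of Igkc ended without any of these (adjusted p up to 0.406), that of Syne2 without library 1 or 3 (up to 0.284), and that of AC148019.2 without any of them or mutant library 1, 2, 3, 4, 7 or 8 (up to 0.58).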

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

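The interaction tests were planned; the tests of explanations, the log scale of the search for outlying libraries and the gene counts over other splits were chosen after the results were seen. The effect of transduction in VIP nuclei differed between Kir2.1 and the mutant in 85 genes (interaction test). In simulation the test called 25 unchanged genes and 13% and 45% of genes changed 2-fold and 4-fold. The count was 719 without the count filter and as low as 48 with 1 library left out. In log2 units the difference was -4.02 for Npy, -1.93 for Mlip, -1.96 for Pde10a, -4.04 for Cnmd, -1.40 for Egfr, -3.04 for Nr4a1, -1.81 for Pthlh, -2.39 for Penk, -1.64 for Dlx6os1 and -1.66 for Vip. It was 1.36 for Fbln2, 1.44 for Kcnc1, 1.73 for Fdps, 0.98 for Socs2 and, as a fitted value that is no bound because the transduced mutant group was at 0, 11.89 for Ndp (12.84 without non-transduced Kir2.1 library 6, and 10.89 and 11.25 without non-transduced mutant libraries 2 and 8). Ndp did not pass with a replicate block within a vector (7.50, edgeR adjusted p = 0.463). The log2 fold change of Kir2.1 against mutant differed between VIP nuclei and neurons in 58 genes (274 without the count filter, 104 with DESeq2, and as few as 36 with 1 library left out). A different share of interneuron nuclei in the neuron sort cannot be told apart from a different response here. The difference of log2 fold changes was 1.10 for R3hdm1, 4.01 for Egfr, 1.91 for Grik1, 0.99 for Sidt1, 5.62 for Cldn1, 3.04 for Prox1, 0.88 for Camk2a and 1.37 for Gabra4, and -2.02 for Cdh13, -1.53 for Clstn2, -1.76 for Trpc6, -1.51 for Galnt14, -2.34 for Hs3st4 and -3.68 for Npy. Cldn1 and Npy did not pass with a replicate block within a vector (edgeR adjusted p = 0.074 and 0.165).

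For most gene counts, 1 of 100 splits of the same libraries, the real one, gave as many genes. Such splits mix the compared groups and may part libraries of the same animal, so they make chance less likely but do not exclude it. Kir2.1 against mutant gave 294 genes in transduced VIP nuclei (highest other split 2) and 898 in transduced neurons (highest other 0). Transduction gave 163 genes with Kir2.1 (highest other 5) and 2 with the mutant (highest other 1), its interaction with vector 85 (highest other 2), and the interaction of vector and population 58 (highest other 3). VIP against all nuclei gave 6266 (highest other 3), and mutant against no AAV 48 in all nuclei (highest other 4) and 6 in transduced VIP nuclei (highest other 1). The count of 6 fell to 1 without VIP library 3 of the mice without AAV. For the 3 comparisons with 0 genes all 100 splits give as many by construction, so the splits say nothing of chance there: Kir2.1 against mutant in non-transduced VIP nuclei (highest other 1) and all non-transduced nuclei (highest other 2), and non-transduced mutant VIP nuclei against those without AAV (highest other 4). For these edgeR gave 1843, 1289 and 2709 genes at an unadjusted p under 0.05, DESeq2 6, 2 and 48 past the threshold, and limma voom, run for the former pair, 0 in each.

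Some markers of VIP and GABAergic identity fell with Kir2.1 in transduced VIP nuclei. The 6 past the threshold, chosen for having fallen, had a median log2 fold change of -1.42. Over the whole lists the median was -0.31 for 16 VIP markers (12 not past) and -0.48 for 12 pan-GABAergic entries (10 not past). Nuclei of excitatory neurons in the sort were argued against: the fall of Vip would need 66.4% of nuclei without it, whereas all 20 measured excitatory markers, set against their level in transduced Kir2.1 neurons, allowed a median of 1.01% (upper quartile 4.26%). Of these 19 lay below that need, the highest of them at 12.4%, and Camk2a alone lay above it (103%), with a level in transduced Kir2.1 VIP nuclei (987 CPM) near that in the neurons (975 CPM). A response of these genes to the working channel may remain, as a hypothesis found and tested on the same data. Of 15 markers of other interneurons 0 rose and 2 fell past the threshold (7 positive, median -0.05). Pan-GABAergic entries were negative in 10 of 12 (camera adjusted p = 0.00092 with an estimated correlation). These values argue against nuclei of other interneurons, which share the pan-GABAergic genes, as the source of the pan-GABAergic falls. For the fall of Vip such nuclei stay open, as no sort of other interneurons gave a level to set against. A shift between subtypes of VIP neuron was not tested.

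Single libraries stood far from the rest of their group, by the gap to the nearest library, in 12 of 164 groups of values on a log2(CPM + 1) scale. Chance gives about 1 in 20, here 8, and 26 were found on the linear scale. In transduced VIP nuclei with Kir2.1, Fdps was at 32.5 CPM in library 6 (others 58.2 to 100 CPM), Npas4 at 0.255 in library 2 (all others 0) and Fos at 6.55 in library 3 (0 to 1.53). With the mutant, Mlip was at 110 CPM in transduced VIP library 4 (146 to 194), Vip at 730 in transduced VIP library 1 (3150 to 8870) and Rogdi at 51.7 in transduced neuron library 3 (89.2 to 128). Non-transduced Kir2.1 VIP library 9 had Kcnj2 at 1.52 (8.64 to 27.9) and Vip at 1690 CPM (3150 to 5050). Among all non-transduced nuclei, Kcnj2 was at 2.72 in mutant library 8 (11 to 23.1), Egr1 at 0.823 in Kir2.1 library 10 (9.1 to 50) and at 4.84 in mutant library 4 (22.3 to 85.2), and Junb at 0.303 in mutant library 4 (7.92 to 38.8).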

How the results depend on the processing

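The tests without libraries that stand apart and with sex read from expression were chosen after the data were seen. Of 1498 values of named genes under the alternatives, 1452 kept their direction and their side of the threshold, 31 lost the call, 2 gained it and 13 changed sign. With another normalization 189 of 189 kept both. Without the count filter the interaction of vector and transduction gave 719 genes, that of vector and population 274, and non-transduced mutant VIP nuclei against no AAV 4. DESeq2 gave 1382 genes for Kir2.1 against mutant in transduced neurons, 6 in non-transduced VIP nuclei and 2 in all non-transduced nuclei, 104 for the interaction of vector and population, and, for mutant against no AAV, 48 in non-transduced VIP, 63 in transduced VIP and 333 in all nuclei. Non-transduced mutant VIP nuclei against no AAV gave 8 genes without the libraries that stand apart, 7 with labelled sex and 2 with sex by expression as a covariate. In a fit of only the groups compared, where fewer genes passed the filter, they gave 3, transduced mutant VIP nuclei against no AAV 11, and transduction with Kir2.1 105. The other gene counts stayed within 1.5 times of their reported value under these settings; Kir2.1 against mutant in transduced VIP nuclei ran from 226 to 420. Apart from the filter of the fit of compared groups, the cause of these changes was not tested. Besides Vip and Arc, whose values stand with their comparisons, calls ended under at least 1 alternative without a block in some genes, with these adjusted p over the alternatives. With Kir2.1 transduction Gabrb2 ran from 0.00155 to 0.146, Ly6c1 from 0.0265 to 0.0893 and Fos from 0.00893 to 0.136. In transduced neurons Rpl6 ran from 0.0175 to 0.0872 and mt-Nd1 from 0.0116 to 0.0514. Against no AAV, AC148019.2 in transduced VIP nuclei ran from 0.000387 to 0.0806, and Copz2 and Lrrtm1 in all nuclei from 0.00393 to 0.0998 and from 0.00307 to 0.107. The alternative without shallow libraries removed no library and was not run.

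Signs changed only in results that did not pass (smallest adjusted p = 0.777 under alternatives and 0.782 with 1 library left out). In non-transduced VIP nuclei Nptx2 was at -0.37 and Egr1 at -0.089 with labelled sex, and with limma voom Npas4 was at 0.22, Nptx2 at -0.50 and Egr1 at -0.053. In all non-transduced nuclei Vip was at -0.25 with sex by expression, and with voom Igf1 was at 0.23, Fos at -0.44, Vip at -1.86 and Arc at -0.10. Leaving out each library in turn gave -0.20 to 0.23 for Egr1, -0.38 to 0.69 for Nptx2 and -0.048 to 0.20 for Vip in non-transduced VIP nuclei, and -0.30 to 0.005 for Junb in transduced neurons. In all non-transduced nuclei it gave -1.20 to 1.14 for Vip, -0.31 to 0.24 for Arc, -0.22 to 0.94 for Fos, -0.82 to 0.37 for Igf1 and -1.53 to 0.27 for Crh.

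With 1 library left out, gene counts ran from 219 to 429 for Kir2.1 against mutant in transduced VIP nuclei, 639 to 1062 in transduced neurons and stayed at 0 in the non-transduced groups. They ran from 116 to 195 for transduction with Kir2.1, stayed at 2 with the mutant, and ran from 5482 to 6385 for VIP against all nuclei. The interaction of vector and transduction ran from 48 to 112, with 52 and 48 without transduced mutant VIP libraries 2 and 4, and 50 and 52 without non-transduced mutant VIP libraries 3 and 7. The interaction of vector and population ran from 36 to 61, with 38, 38 and 36 without Kir2.1 neuron libraries 3, 4 and 9 and 38 without mutant neuron library 3. Against no AAV, non-transduced mutant VIP nuclei ran from 0 to 1 (1 without VIP library 1 of the mice without AAV), transduced ones from 1 to 6 (2, 3 and 1 without those libraries 1, 2 and 3), and all nuclei from 21 to 63 (21 without library 2 of the mice without AAV). Of 3899 values of named genes, 3745 kept direction and side, 129 lost the call, 1 gained it and 24 changed sign.

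Lists past the threshold with an estimated correlation numbered 5, against 10 with the preset one, for Kir2.1 against mutant in transduced VIP nuclei, 4 against 12 in transduced neurons, 0 against 6 in non-transduced VIP nuclei and 0 against 4 in all non-transduced nuclei. They were 4 against 8 for transduction with Kir2.1, 1 against 5 with the mutant and 5 against 8 for their interaction. The fry test, which does not compare a list with other genes, gave 1 in non-transduced VIP nuclei, 0 in all non-transduced nuclei and 1 for transduction with the mutant. Without the libraries that stand apart, 8 lists passed with the preset correlation for transduction with the mutant and 0 with an estimated one. The other counts with the preset correlation stayed within 1.5 times.

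The labels do not say that libraries of the same replicate number came from the same mouse. Deviations from the group means correlated over 0.1 in 31 of 57 same-numbered pairs within a vector (-0.267 to 0.75, mean 0.125, 28 correlating best with their own number). Between vectors they did in 6 of 34 (-0.257 to 0.339, mean -0.014, 3 best). All 22 combinations of vector and number had a single sex by expression. Within a vector these values point to a shared animal for at least a part of the pairs. The main fits did not model this and treated such libraries as independent. With the number as a replicate block, Kir2.1 against mutant in transduced neurons gave 526 genes and transduction with the mutant 5; the other gene counts stayed within 1.5 times. With the replicate block across vectors, genes called in transduced neurons that did not pass were Lamp5 (adjusted p = 0.0644), Aldh1l1 (0.0984), Stat2 (0.0512), Gabrb2 (0.128), mt-Nd1 (0.112), Rpl6 (0.193) and Bdnf (0.0825). With the block within a vector these were Ly6c1 for transduction with Kir2.1 (0.442), Ndp in its interaction with vector (0.463), and Cldn1 (0.074) and Npy (0.165) in the interaction of vector and population. With the replicate block across vectors Egr1 in non-transduced VIP nuclei was at -0.62, and in all non-transduced nuclei Fos was at -0.07 and Vip at -1.14. Depth limits genes of low count: 3 counts over the 3 libraries of all nuclei without AAV equal 0.167 CPM, and genes at 0 there have only bounds.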

Other observations

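The lists of sterol, neuropeptide, B and plasma cell and T cell genes were written, and their tests and those of both patterns below chosen, after the data were seen. Genes of sterol synthesis and uptake rose with Kir2.1 in transduced VIP nuclei: 12 of 24 passed, 24 of 24 were positive and the median log2 fold change was 1.24 (camera adjusted p = 5.9e-08 with an estimated correlation). Without the 4 members seen first, 8 of 20 rose with a median of 0.99 (8.62e-08). Besides Fdps and Msmo1, Sqle, which makes squalene epoxide, had a log2 fold change of 1.64 ± 0.28 (SE, adjusted p = 0.000136) and the isomerase Idi1 of 2.85 ± 0.69 (0.016), while Hmgcs1 (0.72, 0.14) and Insig1 (1.43, 0.12) did not pass. Between transduced and non-transduced VIP nuclei the list was higher with Kir2.1 (median 0.55, 2 of 24 past, adjusted p = 0.0025 with an estimated correlation) and lower with the mutant (median -0.56, 21 of 24 negative, 0 past, 0.00072), and the interaction passed (median 1.07, 2 of 24 past, 1.47e-05). In transduced neurons 1 of 23 rose (median 0.51, 0.173), and the difference between populations passed as a list (median 0.83, 0 of 24 past, 0.00044). The list did not pass with an estimated correlation in non-transduced VIP nuclei (0.448) or all non-transduced nuclei (0.675). It was lower in transduced mutant VIP nuclei than in VIP nuclei without AAV (median -0.47, 21 of 24 negative, 0 past, 0.00757).

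Neuropeptide and secretory granule genes, several of which also stand in the activity and marker lists, fell in 10 of 26 members with Kir2.1 in transduced VIP nuclei. Their median log2 fold change was -0.15, with 11 positive (adjusted p = 0.00215 with an estimated correlation). Tac2 (0.41, adjusted p = 0.731), Scg2 (0.05, 0.987) and Chgb (-0.11, 0.953) were members that did not pass beside the falls of Npy, Vgf, Penk, Crh and Cck. In the interaction with transduction 7 of 26 were lower (0.000527), and in transduced neurons 5 of 18 fell (0.0296). Between transduced and non-transduced VIP nuclei 7 of 26 fell with Kir2.1 (0.0025), and with the mutant the list did not pass (median 0.37, 0.111).

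Syne2 rose in transduced VIP nuclei of either vector. A response to the working channel was argued against, because the log2 fold change with the mutant vector was 3.34. Reads from the vector, whose labels name a KASH domain, are a candidate source that stayed open: gene counts hold no position within the gene. Within the 4 transduced groups, Syne2 and Kcnj2 (log2 CPM) had Pearson r of 0.852 in Kir2.1 VIP nuclei (permutation p = 0.00181, BH-adjusted 0.0066; Spearman 0.915, p = 0.00047), 0.767 in mutant VIP nuclei (exact permutation p = 0.0174, adjusted 0.0232; 0.833, p = 0.00827), 0.914 in Kir2.1 neurons (exact permutation p = 0.0033, adjusted 0.0066; 0.929, p = 0.00223) and 0.606 in mutant neurons (exact permutation p = 0.124, adjusted 0.124; 0.643, p = 0.0962). Without the 2 libraries farthest from the median of Kcnj2 these were 0.781, 0.823, 0.813 and 0.497.

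In all nuclei, 45 genes were higher in mutant-injected mice than in mice without AAV (48 genes called in all, against 333 by DESeq2), with a median log2 fold change of 4.52, also with 13 of them at their bounds; 4 were interferon and innate immune genes, a list of 25 with a median of 2.77 that did not pass with an estimated correlation (adjusted p = 0.206). A larger share of microglial RNA was argued against as the whole source, as 16 microglia markers had a median of 0.489 (quartiles 0.151 and 0.969). Male libraries alone (4 against 3) gave a median of 3.99 with 45 of 45 positive. These libraries were among those that chose the 45 genes, so the choice itself favours positive values. The values therefore lean against sex as the whole source without excluding it. RNA of B and plasma cells is a candidate source of a part: Igkc was above all 6 libraries without AAV in 73 of 73 injected libraries, though the highest of the former, 2.19 CPM, and the lowest of the latter, 2.21 CPM, nearly met, and 15 of 16 measured B and plasma cell genes were positive, 2 past the threshold (median 6.498, or 4.42 with 7 genes at 0 without AAV set to their bounds; adjusted p = 0.0865 with an estimated correlation, 0.0438 and 0.00757 for non-transduced and transduced VIP nuclei). In all nuclei of mutant-injected mice Igkc was at 165 ± 236.5 CPM, Cd74 at 52.9 ± 32.4 and Jchain at 26.8 ± 24.4, and a sort for tagged VIP nuclei, where Igkc was also found (39.3 ± 21.7 CPM in non-transduced ones), would remove such cells but not free RNA. The batch of the libraries without AAV was not given, so batch and injection cannot be told apart, and T cell genes did not pass as a list (median 2.77, 6 of 7 positive, adjusted p = 0.349 with an estimated correlation).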
